A study of Mus musculus with 12 samples.

How the data were processed

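Total RNA of MIN6 cells was analysed in 12 libraries, 3 in each of 4 groups: control, 16 h without amino acids (starved), amino acids given back for 3 h (re-added), and amino acids given back together with Rap for 3 h. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. They also do not give the composition of the amino acid free medium, its glucose and serum, the dose of Rap, or how long the cells of the last 2 groups had been without amino acids before re-addition. Per the labels' protocols, RNA was extracted with TRIzol and a spin column kit and sequenced as paired ends of 150 bases.

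The main values are raw read counts per gene and library, deposited by the authors as 1 table per library. Per the file headers, each row is an Ensembl mouse gene with its exon coordinates, strand and summed exon length. Per the submitters' processing notes, the genome build was GRCm38.p6, and Subread 2.0.1 and limma 3.46.0 were used, with no role stated for either. The aligner, the strand setting of the counting and the annotation release are not given in the sources used here. Reads of genes that overlap, of antisense partners and of near-identical copies therefore cannot be told apart with certainty. The authors also deposited a table of TPM values (counts per length of exon, scaled to a common total) with gene names. Its values equal the counts divided by exon length and rescaled to a fixed sum per library within 5.0e-05, so it carries no depth and no scaling between libraries. Its 12 columns were assigned to libraries through the column headers of the count files, and 0 columns were left unassigned. Gene names come from that table, and 174 genes had none. Coordinates are those of the count files, from the first exon base to the last over all transcripts, counted from 1.

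Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group design (minimum count 10, minimum total 15), which left 16844 of 49315 genes holding 99.9% of the counts. Library sizes were scaled by TMM. All 12 libraries entered 1 quasi-likelihood fit with 4 group means and 8 residual degrees of freedom, and each comparison was a contrast in it, with Benjamini-Hochberg adjustment and a threshold of 0.05. The main comparisons were starved against control, re-added against starved, and Rap against re-added. The secondary ones were Rap against starved and re-added against control. CPM values use the TMM-scaled library sizes, except those of the marker lists, Sftpc, Xist, Rn7sk and other values given library by library, which use raw totals. Library totals ran from 18555958 to 25631056 counted reads, so a gene at 5 CPM rests on 92.8 to 128 reads in a library, and the spread between replicates, not counting error, sets the precision of most values.

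A total of 33 gene lists was fixed from general knowledge before the data were examined, as were the 3 main comparisons, the tests and the alternatives, apart from 3 alternatives named as added. Some lists share genes, such as the ATF4 response list with those of amino acid synthesis, amino acid transporters and p53 targets. The results of such lists are not independent. Lists were tested with camera (preset correlation 0.01) on the edgeR fit, adjusted over 33 lists and 3 main comparisons together, 99 tests. Beside it camera was run with an estimated correlation and fry from limma 3.58.1. Of the lists, 22, 18 and 17 passed in the 3 main comparisons, and 4, 6 and 7 also did so with an estimated correlation. Named genes follow a rule set before the data were examined. It takes Pdx1, Ins1, Ins2 and Mafa always, the 6 rising and 6 falling genes with the largest change among called genes of at least 5 CPM that have a proper symbol and non-overlapping groups (3 of each in secondary comparisons; chance alone separates 3 libraries from 3 in 10% of genes), the 3 members with the smallest adjusted p in each of the 8 lists with the smallest camera p, and the 6 leading genes of each overlap. Some genes that the rule takes are not used here.

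Overlaps between comparisons are given with the value for independent lists. It is the product of the counts of both comparisons in each direction over the genes tested, summed over both directions. Where libraries are shared, 20 simulated sets of unchanged groups are given as well. The edgeR and DESeq2 routines were tested on simulated counts of 16480 genes, with 200 changed genes in the starved and 200 other genes in the Rap group. In the simulated starved group the 34 genes of the ATF4 list were also raised, by 0.8 on the log2 scale. They count as true changes, and edgeR found 73.5% of them. Camera at the preset correlation also called 2 other lists of the 33 in those data. In simulated starved against control data edgeR found 22.4% of genes changed by 0.5 on the log2 scale, 57.6% of those changed by 1 and 76.6% of those changed by 2, and 0.781% of its 128 calls were false. In simulated Rap against re-added data these shares were 21.5%, 57.6% and 84.4%, with 3.64% of 110 calls false. DESeq2 called more genes that had not been changed: 20.8% of its 192 calls in the first data and 28.6% of its 168 calls in the second were false.

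Alternatives set in advance were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a stricter filter (1 CPM in 3 libraries), only the libraries of the 2 groups compared, the replicate number as a block, limma on log2(TPM + 1) and log2(TPM + 0.1) with a mean TPM of at least 0.5 or no minimum, and leaving out each of the 12 libraries. On a log2(TPM + 1) scale the change of low genes is understated. The alternatives added after the data had been seen were leaving out the 4076 tested follower genes, libraries matched on other-cell markers (starved replicate 1 against the controls; starved replicate 2 against re-added replicates 2 and 3 and the Rap replicates; starved replicate 3 and re-added replicate 1 left out), and the log2 of the marker sum as a covariate. In the matched libraries each comparison with starved cells holds 1 starved library, and the lone sample is assumed to vary like the other groups. Follower genes rise with the summed fibroblast, leukocyte and endothelial markers within the starved and within the re-added libraries, in CPM on raw library totals. The slope over the 3 libraries must give over 10% of their control level, with no bound on its error. On TMM-scaled CPM some of them, such as Fbxo32, Ypel4, Tcp11l2 and Rps4x, were highest in starved replicate 2, where the markers were lowest among the starved libraries.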

Results

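Transcript levels were measured by RNA sequencing in MIN6 cells, a mouse insulinoma line that secretes insulin and is used as a model of the pancreatic β-cell. The 12 libraries fall into 4 groups of 3. The control group was not treated, the starved group was kept without amino acids for 16 h, the re-added group was given amino acids back for 3 h, and the last group was given amino acids back together with "Rap" for 3 h. The labels do not spell out Rap. The series title names the kinase complex mTORC1, which senses amino acids, and the design text names Pdx1, the homeobox factor that drives insulin gene transcription in β-cells. The libraries held between 18555958 and 25631056 counted reads. Of 49315 genes in the count files 16844 passed the filter on low counts, and 12103 of these differed among the 4 groups in 1 F test of edgeR at an adjusted p under 0.05. Values are CPM, read counts scaled to a common library total, given as mean ± SD with n = 3, and adjusted p-values are from the quasi-likelihood test of edgeR.

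Transcripts of cell types other than β-cells were present at levels that differed between libraries of the same group. The markers of fibroblasts, leukocytes and endothelium, fixed as lists before the data were examined, summed to 1397, 1675 and 1610.0 CPM in the control libraries. They summed to 1372, 108 and 651 CPM in the starved libraries, to 579, 107 and 109 CPM in the re-added libraries, and to 109.5, 111 and 103 CPM in the Rap libraries. Sftpc, which encodes surfactant protein C of the lung, also differed between libraries, with 635, 751 and 735 CPM in the control libraries, 608, 30.3 and 295 CPM in the starved libraries, 279.7, 31.7 and 19.9 CPM in the re-added libraries, and 16.3, 14.4 and 12.6 CPM in the Rap libraries. The first principal component of all tested genes held 72.2% of the variance, and its rank correlation with these markers over the 12 libraries was 0.88, given as a description without a test. Within both the starved and the re-added groups, 4076 of the 16844 tested genes rose with these markers. Their slope would give over 10% of their control level. They are called follower genes here. The slope rests on raw library totals and 3 libraries a group, and its error was not tested, so noise can make a gene a follower. On TMM-scaled CPM the follower gene Fbxo32 stood at 39.1, 43.3 and 37.7 in starved replicates 1, 2 and 3, and so did not rise with the markers there. Each comparison was also run without the follower genes. All but re-added against control were also run with libraries of like marker levels. Both alternatives were chosen after the data had been seen. The matched libraries leave 1 starved library in each comparison with starved cells, replicate 1 against control and replicate 2 against re-added or Rap cells, and this lone sample is assumed to vary like the other groups.

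**Figure D1:**
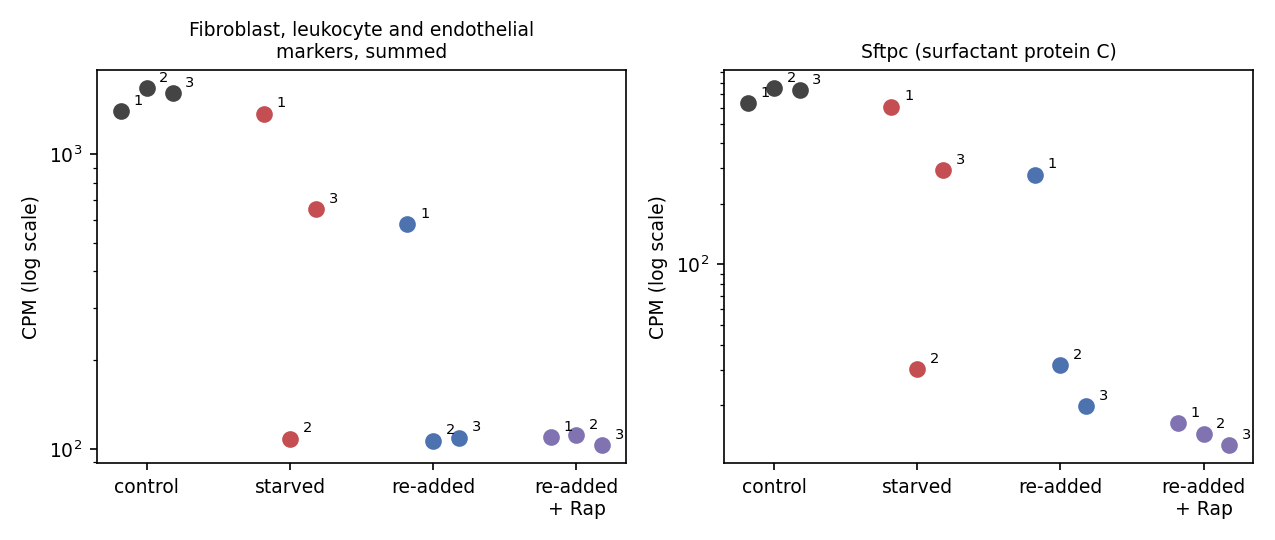
Summed CPM of the fibroblast, leukocyte and endothelial marker lists (left) and CPM of Sftpc (right) in each library, on log axes; each point is 1 library and the small number is its replicate number. The marker sum lies at 1372 CPM in starved replicate 1 and at 108 CPM in starved replicate 2, and between 103 and 111 CPM in the Rap libraries.

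Pdx1 (chromosome 5, 147269959 to 147275848, plus strand, GRCm38.p6) was measured at 627 ± 25.3 CPM in control cells and at 410.0 ± 40.9 CPM in starved cells (SD, n = 3), and this fall passed the test (log2 fold change -0.61, SE 0.08, adjusted p = 8.8e-05). It stood at 476 ± 12.9 CPM in the re-added group and at 505 ± 0.535 CPM in the Rap group. The rise on re-addition was small (log2 fold change 0.22, SE 0.07, adjusted p = 0.0399). It no longer passed without control replicate 1, re-added replicate 2 or 3 or any of the Rap replicates (0.20 to 0.22 on the log2 scale), or in libraries matched on the other-cell markers, where the change was 0.18. Nor did it pass with no filter on low counts (0.23), by limma on the TPM values (0.20) or with the marker sum as a covariate (0.15). Rap against re-added gave 0.08 (SE 0.07, adjusted p = 0.546), which did not exceed the replicate spread.

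The insulin genes and Mafa, another activator of insulin transcription, were also lower in starved cells. Ins1 (chromosome 19, 52264323 to 52265456, plus strand) went from 3572 ± 683 to 2104 ± 69.7 CPM (adjusted p = 0.000467). Ins2 (chromosome 7, 142678656 to 142743381, minus strand, as the files give it) went from 26560.1 ± 5579.9 to 18983 ± 941 CPM (log2 fold change -0.48, adjusted p = 0.00857), a change that shrank to -0.30 without control replicate 2 and did not pass on the TPM + 1 values with no minimum (adjusted p = 0.502). Ins1 and Ins2 are close copies of each other, so their split of the reads is uncertain. Mafa (chromosome 15, 75746843 to 75747922, minus strand) went from 401 ± 83.05 to 187 ± 93.03 CPM (log2 fold change -1.10, adjusted p = 0.00967), and in the matched libraries, with 1 starved library, the log2 fold change was -1.81. None of Ins1, Ins2 and Mafa passed the test on re-addition or with Rap, with adjusted p between 0.0787 and 0.748. For Mafa on re-addition this rested on starved replicate 3: the log2 fold change was 0.68 with it and 1.19 without it, where it passed. Of 16 textbook target genes of PDX1, 1 rose and 9 fell in starved against control (median log2 fold change -0.52, camera adjusted p = 0.000507, and adjusted p = 0.213 with an estimated correlation). The 16 include Pdx1 itself, Ins1, Ins2 and Mafa, so the falls in this list are in part those given above. On re-addition 7 rose and 3 fell, and with Rap none of the 16 passed over all genes or over the list alone.

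The first comparison asked what 16 h without amino acids changed. Of the lists, 20 of 26 glycolysis genes, all 25 cholesterol genes and 27 of 36 respiratory chain genes fell, and 28 of 34 ATF4 response genes, 15 of 27 amino acid transporter genes and 25 of 41 lysosome genes rose. Single genes changed by over 10-fold. Ldha (chromosome 7, 46841475 to 46855627, plus strand), the lactate dehydrogenase that β-cells keep low, fell from 2691 ± 285 to 205 ± 0.942 CPM (log2 fold change -3.71, SE 0.09, adjusted p = 1.7e-10). Slc16a3 (chromosome 11, 120948480 to 120960868, plus strand), a lactate exporter, fell from 718 ± 31.7 to 59.5 ± 0.694 CPM, and Ak4 (chromosome 4, 101419277 to 101466995, plus strand), a mitochondrial adenylate kinase, from 45.2 ± 5.49 to 1.47 ± 0.217 CPM. In total 6559 genes passed the test, 4101 higher and 2458 lower, and 516 rose and 447 fell by at least 2-fold.

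The glycolysis and HIF1 target list moved furthest: 20 of its 26 tested members fell and none rose (median log2 fold change -1.25, camera adjusted p = 3.1e-53). With an estimated correlation its adjusted p was 0.000496, and 0 rose and 21 fell adjusted over the list alone. Besides Ldha, the glucose transporter gene Slc2a1 fell from 145 ± 6.94 to 28.02 ± 1.12 CPM and the phosphoglycerate kinase gene Pgk1 from 1905 ± 185 to 356 ± 19.4 CPM. All 25 members of the cholesterol synthesis and uptake list fell (median log2 fold change -0.77, camera adjusted p = 4.8e-26, and adjusted p = 0.0115 with an estimated correlation), adjusted over all genes and over the list alone. Among them, Cyp51 fell from 194 ± 16.3 to 78.8 ± 6.76 CPM and Hmgcs1 from 88.3 ± 1.91 to 44.3 ± 1.15 CPM.

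Of the 34 genes of the ATF4 and amino acid response list, 28 rose and 1 fell (median log2 fold change 0.82, camera adjusted p = 2.9e-21, and adjusted p = 0.0152 with an estimated correlation), with the same counts adjusted over the list alone. Chac1 (chromosome 2, 119351229 to 119354381, plus strand), which degrades glutathione, rose from 33.5 ± 2.02 to 137 ± 14.6 CPM (log2 fold change 2.03, SE 0.10, adjusted p = 1.1e-07), and the transcription factor gene Atf5 from 232 ± 28.8 to 882 ± 85.3 CPM. The member that fell was Ddit4, which encodes an inhibitor of mTORC1, from 214 ± 8.11 to 95.3 ± 2.39 CPM. Amino acid transporter genes rose in 15 of 27 cases and fell in 1 (median log2 fold change 0.52, camera adjusted p = 8.8e-07, but adjusted p = 0.213 with an estimated correlation). Slc38a2 rose from 172 ± 23.1 to 401 ± 37.01 CPM, Slc7a1 from 56.1 ± 11.4 to 155 ± 16.8 CPM and Slc38a7 from 23.3 ± 1.29 to 51.4 ± 3.16 CPM. Slc38a2 and Slc7a1 are also in the ATF4 list. In the lysosome and autophagy list 25 of 41 genes rose and none fell (median log2 fold change 0.39, camera adjusted p = 2.6e-11, but adjusted p = 0.226 with an estimated correlation); upper-quartile scaling gave a median of 0.24. Flcn, which acts on the Rag GTPases of the mTORC1 pathway, rose from 37.7 ± 2.3 to 112 ± 12.5 CPM, Gabarapl1 (chromosome 6, 129533160 to 129542346, plus strand), an autophagosome protein gene, from 125 ± 11.6 to 320.5 ± 19.5 CPM and Wipi1 from 335 ± 32.4 to 857 ± 89.7 CPM.

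Ribosomal protein genes were lower as a group by a modest amount: 67 of 79 fell and none rose (median log2 fold change -0.50, camera adjusted p = 4.0e-15, but adjusted p = 0.476 with an estimated correlation). Adjusted over the list alone 71 fell, and the median stayed below 0 under every scaling tried. Rpl27 went from 545 ± 54.7 to 307 ± 23.5 CPM and Rpl7a from 911 ± 123 to 606 ± 22.4 CPM. Ribosomal protein genes have many pseudogenes, so their counts are uncertain where reads could be split. Nuclear genes of the respiratory chain fell in 27 of 36 cases and rose in 1 (median log2 fold change -0.51, camera adjusted p = 1.8e-10, but adjusted p = 0.352 with an estimated correlation). Cycs fell from 238 ± 31.4 to 129 ± 5.39 CPM and Ndufb8 from 465 ± 71.04 to 223 ± 16.96 CPM. Of 15 tested genes that β-cells keep low or that mark progenitors, 5 fell and none rose (median log2 fold change -0.39, camera adjusted p = 1.6e-06, and adjusted p = 0.145 with an estimated correlation). They include Ldha, Ndrg2 (24.2 ± 2.41 to 17.1 ± 0.51 CPM) and the follower gene Acot7 (34.9 ± 2.64 to 9.39 ± 3.5 CPM). Of these 15 genes 10 are follower genes. The median was -0.15 in matched libraries, with 1 starved library, and -0.65 without starved replicate 1.

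Other genes with the largest rises were N4bp2l1, from 6.22 ± 0.173 to 56.4 ± 5.24 CPM, Inhba, the activin subunit gene, from 9.05 ± 0.876 to 53.3 ± 2.39 CPM, and Rnf152, a lysosomal ubiquitin ligase gene, from 3.19 ± 0.338 to 17.8 ± 3.999 CPM. Sphk1, the sphingosine kinase gene, rose from 4.72 ± 0.174 to 26.1 ± 4.28 CPM and Man1a, a Golgi mannosidase gene, from 108 ± 11.96 to 588 ± 60.4 CPM. Their adjusted p lay between 1.2e-08 and 4.6e-06. The small nuclear RNA gene Rn7sk also met the rule (log2 fold change 3.15, adjusted p = 0.0198), but its level in starved replicate 2 alone was 34.8 CPM against 3.15 and 2.74 CPM, and without that library the change was 0.85 and did not pass. Nor did it pass without control replicate 1 (2.88) or 2 (3.08). Large falls were also seen for Meltf (chromosome 16, 31878810 to 31899020, plus strand), the melanotransferrin gene, from 7.82 ± 0.696 to 0.866 ± 0.213 CPM, Fam162a from 178 ± 33.3 to 22.9 ± 1.5 CPM, and Trpm5, a cation channel gene of β-cells, from 112 ± 14.3 to 15.8 ± 2.33 CPM. The share of calls that were higher was 62.5% in the main test and 44.6% with upper-quartile factors (2961 higher and 3679 lower, with the median over all genes at -0.13). It was 72.3% with limma on the TPM values (median 0.12), which changes the tool and the filter besides the scaling, 52.4% without the follower genes and 51.8% without starved replicate 1. With libraries matched on the other-cell markers, where starved replicate 1 is the lone starved sample and is assumed to vary like the other groups, 3417 genes passed, and 4199 with only the 6 libraries of the comparison.

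**Figure D2:**
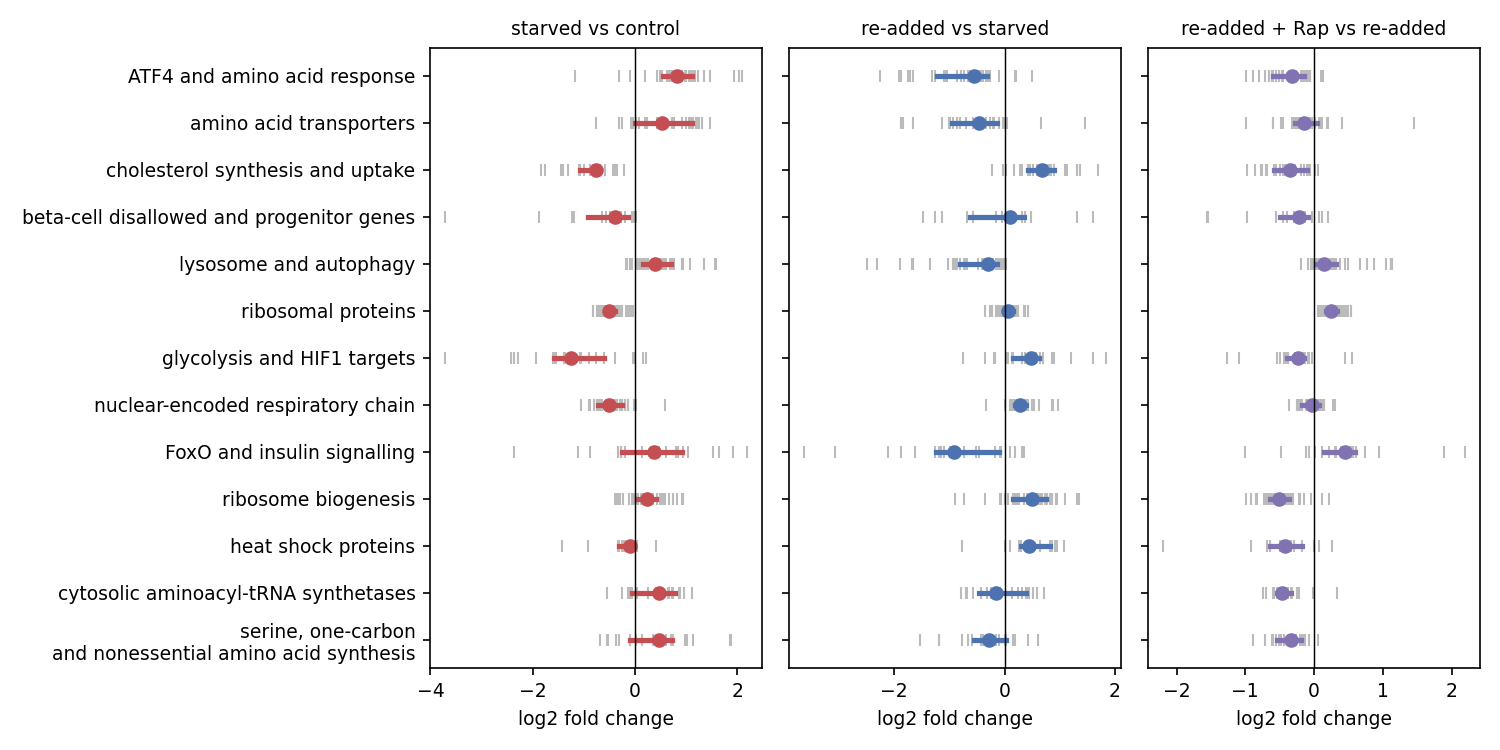
Log2 fold changes of the members of the gene lists described here in the 3 main comparisons; each tick is 1 gene, the dot is the median of the list and the bar its interquartile range. The glycolysis and HIF1 target list has medians of -1.25, 0.48 and -0.24 in starved against control, re-added against starved and Rap against re-added.

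The second comparison asked what giving amino acids back for 3 h changed. The genes that fell include 27 of 34 ATF4 response genes, 26 of 41 lysosome genes and 14 of 22 FoxO list genes, and those that rose 21 of 25 cholesterol genes, 26 of 42 ribosome biogenesis genes, 17 of 26 glycolysis genes and 13 of 17 heat shock protein genes. Klhl24 (chromosome 16, 20097554 to 20127744, plus strand), which encodes an adaptor of a ubiquitin ligase, fell from 116 ± 12.6 to 7.76 ± 2.07 CPM (log2 fold change -3.90, SE 0.21, adjusted p = 1.5e-07). Meltf rose from 0.866 ± 0.213 to 11.1 ± 0.359 CPM (log2 fold change 3.66, SE 0.20, adjusted p = 1.5e-07), and Ak4 from 1.47 ± 0.217 to 13.2 ± 0.354 CPM. In total 6275 genes passed the test, 3100 higher and 3175 lower, against 3856 higher and 2823 lower with upper-quartile factors and 3013 higher and 3841 lower without re-added replicate 1.

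Of the cholesterol list 21 of 25 genes rose and 1 fell (median log2 fold change 0.67, camera adjusted p = 9.2e-17, and adjusted p = 0.0152 with an estimated correlation). Hmgcs1 (chromosome 13, 119690462 to 119708086, plus strand) rose to 114 ± 5.4 CPM and Cyp51 to 168 ± 1.55 CPM. In the ATF4 list 27 of 34 fell and 1 rose (median log2 fold change -0.56, camera adjusted p = 1.7e-16, and adjusted p = 0.0199 with an estimated correlation). Chac1 fell to 36.3 ± 1.19 CPM, Atf5 to 262 ± 11.2 CPM and Slc38a2 to 109 ± 4.27 CPM. Lysosome and autophagy genes fell in 26 of 41 cases and rose in none (median log2 fold change -0.30, camera adjusted p = 5.1e-16, but adjusted p = 0.145 with an estimated correlation). Gabarapl1 reached 64.7 ± 2.46 CPM, Flcn 19.9 ± 0.931 CPM and Map1lc3b, which encodes the autophagosome protein LC3B, 76.97 ± 2.74 CPM against 170.0 ± 11.3 CPM in control. In the glycolysis list 17 of 26 rose and 1 fell (median log2 fold change 0.48, camera adjusted p = 6.4e-12, and adjusted p = 0.0152 with an estimated correlation), with Slc2a1 at 99.9 ± 4.27 CPM, Ldha at 628 ± 19.4 CPM and P4ha1, a collagen prolyl hydroxylase gene, at 271 ± 5.22 CPM from 117 ± 6.17 CPM.

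Ribosome biogenesis genes rose in 26 of 42 cases and fell in 3 (median log2 fold change 0.49, camera adjusted p = 1.9e-10, but adjusted p = 0.145 with an estimated correlation). Rrp12 (chromosome 19, 41862852 to 41896153, minus strand), a factor of ribosomal RNA maturation, rose from 25.6 ± 1.2 to 65.5 ± 0.965 CPM, Bop1 from 49.7 ± 2.73 to 106 ± 2.51 CPM and Bysl from 29.5 ± 1.91 to 73.6 ± 3.52 CPM. Of 17 heat shock protein genes 13 rose and none fell (median log2 fold change 0.44, camera adjusted p = 9.5e-08, and adjusted p = 0.0181 with an estimated correlation). Hspa8 rose from 1340.0 ± 87.9 to 2824 ± 126 CPM, Bag3 from 62.3 ± 4.01 to 110.1 ± 4.13 CPM and Dnaja1 from 227 ± 15.2 to 356 ± 6.89 CPM. In the FoxO and insulin signalling list 14 of 22 fell and none rose (median log2 fold change -0.92, camera adjusted p = 3.4e-09, and adjusted p = 0.0152 with an estimated correlation), and 1 rose and 14 fell adjusted over the list alone. Txnip fell from 334 ± 24.7 to 77.4 ± 5.07 CPM, Ccng2 from 47.3 ± 3.01 to 12.9 ± 1.73 CPM and the follower gene Fbxo32, a ubiquitin ligase gene of muscle atrophy, from 40.02 ± 2.93 to 4.75 ± 0.579 CPM. The list holds 7 follower genes, and its median was -0.48 without them. Respiratory chain genes rose in 15 of 36 cases and fell in 1 (median log2 fold change 0.27, camera adjusted p = 1.4e-05, but adjusted p = 0.533 with an estimated correlation). Cycs rose to 234 ± 15.96 CPM and Sdhb to 151 ± 8.97 CPM from 82.3 ± 4.75 CPM.

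Further genes with large rises on re-addition were Mest, an imprinted gene, from 2.96 ± 0.616 to 22.3 ± 2.27 CPM, and Aass, the first enzyme of lysine breakdown, from 3.85 ± 0.334 to 17.3 ± 0.407 CPM. Arrdc3 rose from 19.6 ± 1.52 to 78.4 ± 2.07 CPM. Sphk1 fell from 26.1 ± 4.28 to 1.81 ± 0.249 CPM, Klf11 from 52.97 ± 5.63 to 5.28 ± 0.629 CPM and the follower gene Ypel4 from 21.3 ± 1.28 to 2.65 ± 0.421 CPM. Xist, the RNA of the inactive X chromosome, also met the rule (adjusted p = 0.00308). It stood at 22.2, 1.997 and 19.5 CPM in the starved libraries and at 0.0985, 0.0946 and 1.32 CPM in the re-added libraries, a few reads in some of them, so no fold is given. It did not pass in libraries matched on the other-cell markers (adjusted p = 0.274) or by limma-voom (adjusted p = 0.0743). With those matched libraries 3552 genes passed in this comparison, with starved replicate 2 as the lone starved sample, assumed to vary like the other groups.

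Of the genes called in both of these comparisons, 3129 moved in opposite directions and 325 in the same direction. Of the 3129, 1228 were lower in starved cells and higher on re-addition and 1901 were higher in starved cells and lower on re-addition, while upper-quartile factors gave 1944 and 1457, so which set is larger depends on the scaling. Independent lists would give 1225. The starved libraries are shared by both comparisons. In 20 simulated sets with no change the mean was 0 such genes, but sets with no change yield hardly any calls, so this does not measure what the shared libraries add to the 3129. Across genes the covariance of the log2 changes was -0.00527 against a simulated -0.0611, and the Pearson correlation was -0.01 against a simulated -0.50. Without the follower genes the covariance was -0.177 and the correlation -0.49. The simulated values cover all tested genes, and none were computed for the set without followers. Genes are not independent replicates, and part of any excess may come from the shared libraries. The count in opposite directions was 3505 in a fit without the follower genes and 2849 with the marker sum as a covariate. Meltf, Ak4, N4bp2l1, Rnf152 and Sphk1 were among the genes with the largest changes in both, as was Rn7sk, which rested on starved replicate 2. Matched libraries, which take starved replicate 1 in the first comparison and replicate 2 in the second and so share none, gave 1435 genes in opposite directions and 47 in the same direction, against 339 for independent lists. Each of these 2 starved libraries is a lone sample, assumed to vary like the other groups.

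The third comparison asked what Rap changed while amino acids were given back. The genes that fell include 31 of 42 ribosome biogenesis genes, 17 of 20 aminoacyl-tRNA synthetase genes, 13 of 25 cholesterol genes and 14 of 34 ATF4 response genes. Those that rose include 10 of 22 FoxO list genes, 10 of 41 lysosome genes and 11 of 79 ribosomal protein genes. Klhl24 rose from 7.76 ± 2.07 to 48.4 ± 3.26 CPM (log2 fold change 2.64, SE 0.21, adjusted p = 1.8e-05), which compares with 116 ± 12.6 CPM in starved cells. Rrp12 fell from 65.5 ± 0.965 to 32.9 ± 0.708 CPM (log2 fold change -0.99, SE 0.07, adjusted p = 1.3e-05), near its level of 26.7 ± 2.04 CPM in control. In total 1344 genes passed the test, 766 higher and 578 lower, and 100 rose and 7 fell by at least 2-fold.

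Ribosome biogenesis genes fell in 31 of 42 cases and rose in none (median log2 fold change -0.51, camera adjusted p = 1.2e-37, and adjusted p = 0.0152 with an estimated correlation), and 1 rose and 37 fell adjusted over the list alone. Grwd1 fell from 59.3 ± 2.21 to 31.4 ± 1.31 CPM and Bop1 to 74.8 ± 3.61 CPM. Of 20 cytosolic aminoacyl-tRNA synthetase genes 17 fell and 1 rose (median log2 fold change -0.46, camera adjusted p = 2.3e-22, and adjusted p = 0.0378 with an estimated correlation). Farsb fell from 80.1 ± 3.07 to 47.9 ± 2.12 CPM, Hars from 117 ± 0.886 to 81.03 ± 1.45 CPM and Nars from 187 ± 0.529 to 125 ± 2.82 CPM. In the ATF4 list 14 of 34 fell and none rose (median log2 fold change -0.33, camera adjusted p = 1.8e-13, and adjusted p = 0.0311 with an estimated correlation). Atf4 itself fell from 304 ± 9.26 to 192 ± 12.4 CPM and Eif4ebp1, which encodes a translation repressor and mTORC1 substrate, from 29.3 ± 0.0718 to 18.6 ± 0.812 CPM. Genes of serine, one-carbon and nonessential amino acid synthesis fell in 12 of 22 cases and rose in none (median log2 fold change -0.34, camera adjusted p = 8.1e-13, but adjusted p = 0.0519 with an estimated correlation). Shmt2 fell from 142 ± 4.2 to 87.2 ± 2.52 CPM, Mthfd2 from 133 ± 4.25 to 91.4 ± 4.62 CPM and Asns, the asparagine synthetase gene, from 278 ± 11.7 to 195 ± 5.31 CPM. Shmt2, Mthfd2 and Asns are also in the ATF4 list. In the cholesterol list 13 of 25 fell and none rose (median log2 fold change -0.34, camera adjusted p = 2.0e-17, and adjusted p = 0.0152 with an estimated correlation). Hmgcs1 fell to 71.4 ± 3.67 CPM, Cyp51 to 99.2 ± 1.27 CPM and the lanosterol synthase gene Lss to 33.5 ± 0.513 CPM from 60.9 ± 4.81 CPM.

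In the FoxO and insulin signalling list 10 of 22 rose and none fell (median log2 fold change 0.45, camera adjusted p = 5.2e-12, and adjusted p = 0.0152 with an estimated correlation), and 10 rose and 1 fell adjusted over the list alone. Ccng2 rose from 12.9 ± 1.73 to 47.7 ± 5.6 CPM, the mitophagy kinase gene Pink1 from 47.2 ± 2.54 to 78.7 ± 1.12 CPM and the follower gene Fbxo32 from 4.75 ± 0.579 to 21.7 ± 1.71 CPM. Lysosome and autophagy genes rose in 10 of 41 cases and fell in none (median log2 fold change 0.14, camera adjusted p = 3.5e-12, but adjusted p = 0.198 with an estimated correlation), with a median of 0.04 on the TPM values. Atg13, part of the kinase complex that starts autophagy, rose from 74.6 ± 1.36 to 163 ± 0.82 CPM, Gabarapl1 from 64.7 ± 2.46 to 141 ± 5.49 CPM and Map1lc3b from 76.97 ± 2.74 to 159 ± 8.05 CPM. Ribosomal protein genes rose in 11 of 79 cases and fell in none (median log2 fold change 0.25, camera adjusted p = 1.6e-12, but adjusted p = 0.511 with an estimated correlation), with a median of 0.14 on the TPM values. Rpl5 went from 399 ± 19.5 to 579 ± 30.7 CPM, the follower gene Rps4x from 444 ± 31.3 to 645 ± 9.21 CPM and Rps3a1 from 595 ± 14.7 to 813 ± 43.5 CPM. The Rps3a1 call was lost without re-added replicate 2 (log2 fold change 0.46), re-added replicate 3 (0.43) or Rap replicate 3 (0.41).

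Among the genes with the largest changes under Rap, Crebrf, a regulator of the CREB3 factors, rose from 10.8 ± 0.924 to 51.96 ± 1.49 CPM, Coq8a, a gene of coenzyme Q synthesis, from 2.97 ± 0.391 to 14.7 ± 0.273 CPM, and Frat1 from 3.75 ± 0.129 to 17.7 ± 1.03 CPM. The follower genes Tcp11l2 and Ypel4 rose from 2.74 ± 0.582 to 14.99 ± 1.39 CPM and from 2.65 ± 0.421 to 13.8 ± 0.908 CPM. Meltf fell from 11.1 ± 0.359 to 3.94 ± 0.555 CPM and Pfkfb3, an enzyme gene that speeds glycolysis, from 58.7 ± 1.79 to 27.6 ± 2.05 CPM. The follower genes Col6a3 (-1.01, adjusted p = 0.0445), Scd1 (-0.99, adjusted p = 0.0275) and Ddr2 (-0.99, adjusted p = 0.0415) also met the rule on the log2 scale. These calls were lost without re-added replicate 1, re-added replicate 2 or any of the Rap replicates, where the values lay between -1.06 and -0.89 for Col6a3, -1.06 and -0.91 for Scd1, and -1.08 and -0.81 for Ddr2. Col6a3 was also lost without control replicate 1 (-1.01) or 3 (-1.01), starved replicate 3 (-1.04) or re-added replicate 3 (-1.08), Scd1 without re-added replicate 3 (-1.02) and Ddr2 without starved replicate 3 (-1.02). By limma-voom, by limma on the TPM values and with the replicate number as a block Col6a3 (-0.99, -0.84 and -0.99) and Ddr2 (-0.96, -0.59 and -0.98) were lost as well. Against 1344 genes, 665 passed without re-added replicate 2, 635 without re-added replicate 3, 693, 665 and 687 without Rap replicate 1, 2 or 3, and 2058 without control replicate 2. Of the calls 57.0% were higher, against 28.8% with limma on the TPM values (552 higher and 1366 lower), another tool and filter, 45.8% with no filter on low counts and 47.9% of 2046 genes without the follower genes.

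**Figure D3:**
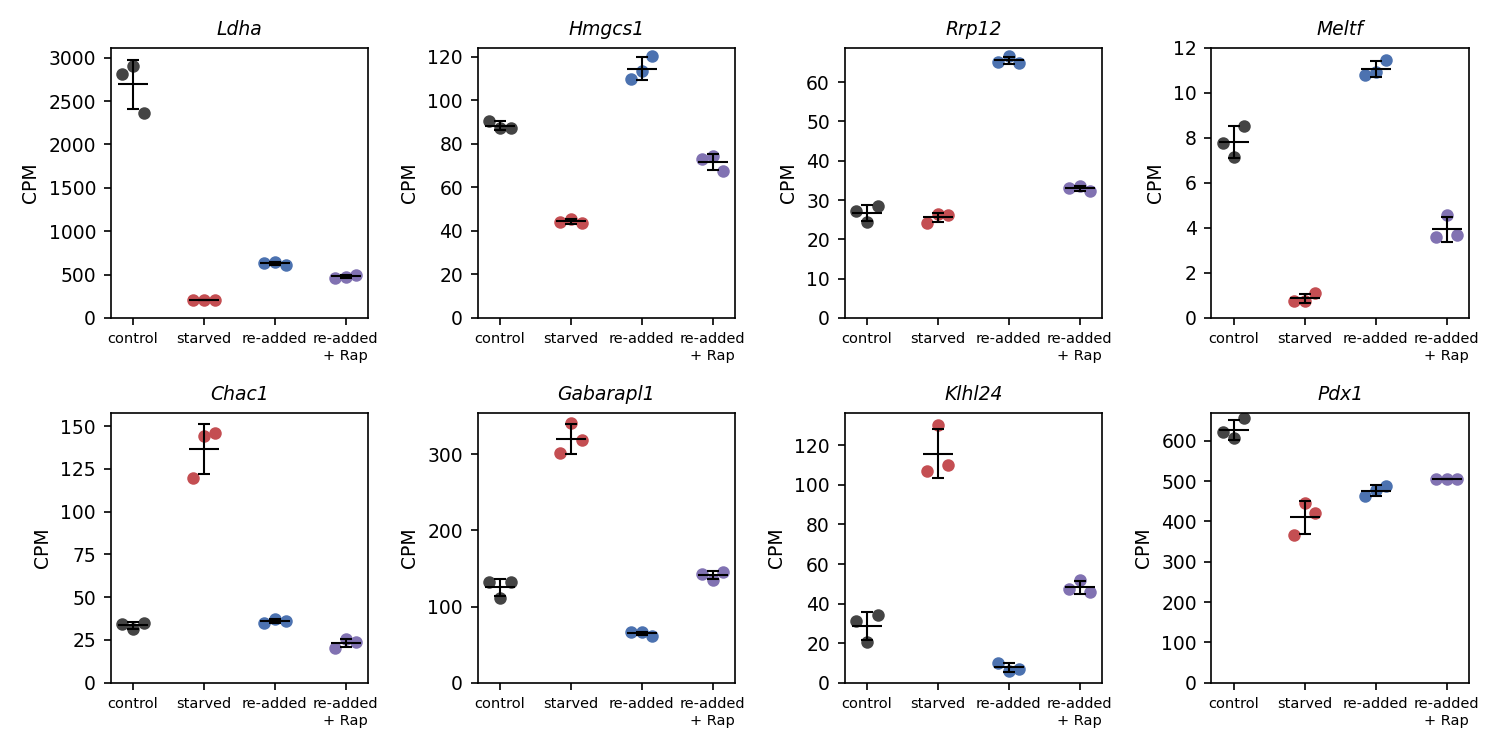
CPM of 8 genes in the 4 groups; each point is 1 library, the horizontal mark the group mean and the bars ± SD (n = 3). Chac1 stands highest in starved cells, at 137 ± 14.6 CPM, while Rrp12 stands highest on re-addition, at 65.5 ± 0.965 CPM, and at 32.9 ± 0.708 CPM with Rap.

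Rap and starvation were compared through pairs of groups that share no library. Of the genes called in both Rap against re-added and starved against control, 631 changed in the same direction (422 higher and 209 lower in both), against 271 for independent lists, and 189 changed in opposite directions. By limma on the TPM values 341 were higher and 400 lower in both, so the excess of higher genes was lost there. The count in opposite directions was 415 by limma on the TPM values, beside 741 in the same direction. DESeq2 gave 357 and 983. Klhl24, Crebrf, Derl3, N4bp2l1 and the follower gene Fbxo32 were higher in both. Derl3, a gene of protein export from the endoplasmic reticulum, measured 6.36 ± 1.26, 19.2 ± 1.93, 13.4 ± 1.32 and 38.7 ± 3.61 CPM in control, starved, re-added and Rap cells. Meltf was lower in both. Across all tested genes the Pearson correlation of the log2 changes was 0.47 and Spearman's rho 0.34, with no p because genes are not independent replicates. The correlation was 0.20 without the follower genes, 0.0822 with matched libraries and 0.12 without re-added replicate 1. A fit without the follower genes gave 937 genes changed in the same direction, against 523 for independent lists. With the marker sum as a covariate 633 did so. The count of genes changed in the same direction was 339 with matched libraries, 361 and 367 without re-added replicate 2 or 3, and 367, 360 and 390 without Rap replicate 1, 2 or 3.

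Between Rap against re-added and re-added against starved, which share the re-added libraries, 840 genes moved in opposite directions and 121 in the same direction, against 251 for independent lists and a mean of 0.1 in 20 simulated sets with no change, which yield hardly any calls and so do not measure what the shared libraries add. Of the 840, 495 were higher with Rap and lower on re-addition, and 345 lower with Rap and higher on re-addition. This balance was not stable, with 367 and 757 by limma on the TPM values, 517 and 571 with the stricter filter, 655 and 662 by DESeq2, 605 and 619 without the follower genes, and 449 and 493 or 427 and 465 without starved replicate 2 or 3. The covariance was 0.136 against a simulated -0.0611, and -0.0644 without the follower genes, with Pearson correlations of 0.27, -0.49 and -0.30. Here too the simulated values cover all tested genes, not the set without followers. The count in opposite directions was 1224 in a fit without the follower genes and 948 with the marker sum as a covariate. Part of the excess may come from the shared libraries. Klhl24, Crebrf, Coq8a and the follower genes Tcp11l2, Ypel4 and Fbxo32 led this set, which held 534 genes with matched libraries, 461 and 458 without re-added replicate 2 or 3, and 484, 482 and 502 without Rap replicate 1, 2 or 3.

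**Figure D4:**
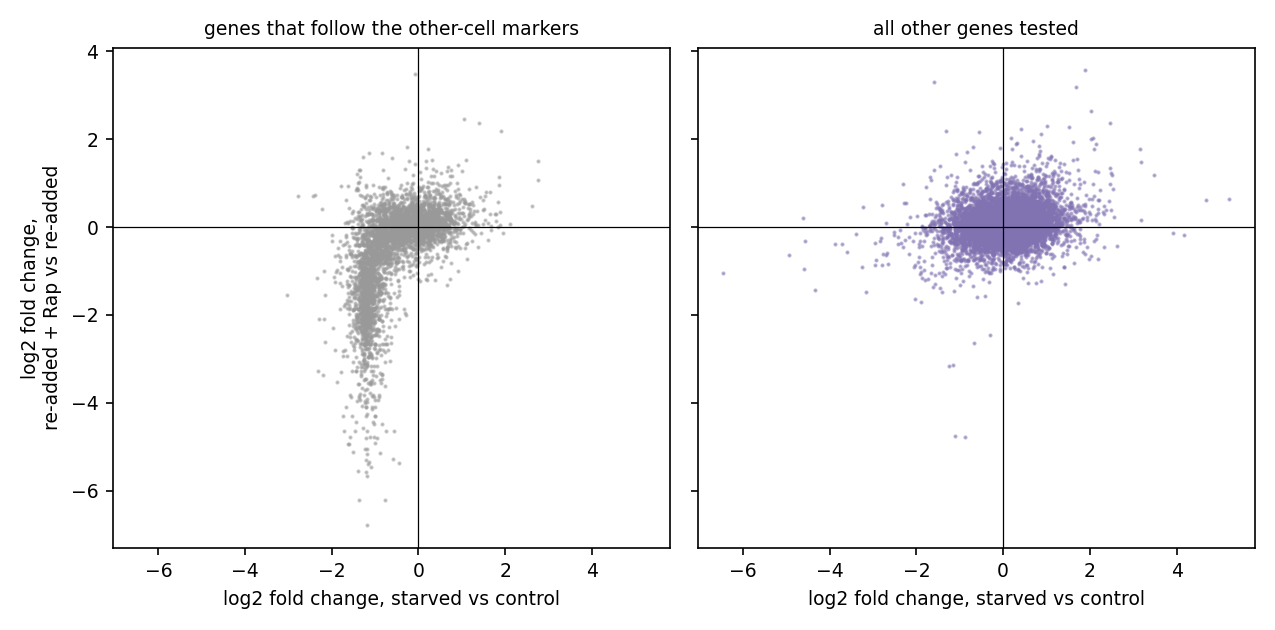
Log2 fold change in Rap against re-added cells (vertical) plotted against that in starved against control cells (horizontal), for the 4076 follower genes (left) and the other 12768 tested genes (right); each point is 1 gene. The Pearson correlation is 0.57 among the follower genes and 0.20 among the others.

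Against starved cells, the cells given amino acids together with Rap had 7424 changed genes, 3399 higher and 4025 lower, and 1635 of the latter are follower genes. Upper-quartile factors gave 4187 higher and 3714 lower and limma-voom 3425 higher and 2953 lower, so the balance is not settled. Mest (2.77), Ak4 (2.51) and Arrdc3 (2.38) rose most on the log2 scale, and Pdx1 was higher by 0.30 (adjusted p = 0.0085), a call lost in matched libraries (0.22, adjusted p = 0.173), by limma on the TPM values (0.18, adjusted p = 0.0736) and with the marker sum as a covariate (0.19, adjusted p = 0.125). The genes that fell most were the follower genes Tgtp1, Chil3 and Ly6c1, from 11.1 ± 10.97, 12.6 ± 11.3 and 11.9 ± 10.7 CPM to 0.0705 ± 0.0347, 0.0862 ± 0.0289 and 0.112 ± 0.149 CPM (adjusted p = 0.00949, 0.00451 and 0.00702), the last levels resting on a few reads, so no fold is given. These 3 calls were lost by limma-voom, with adjusted p = 0.204, 0.185 and 0.173. Matched libraries gave 3709 genes, again with starved replicate 2 as the lone starved sample, and leaving out Rap replicate 3 gave 4940.

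Against control cells, the re-added cells had 8304 changed genes, 4172 higher and 4132 lower, and 369 of the former and 2131 of the latter are follower genes. Mest rose from 3.82 ± 0.405 to 22.3 ± 2.27 CPM, Slc6a12, a betaine and GABA transporter gene, from 2.25 ± 0.315 to 11.3 ± 0.696 CPM and Iqsec3 from 25.9 ± 8.44 to 116 ± 5.83 CPM. Xist fell from 29.9 ± 4.47 to 0.505 ± 0.707 CPM, and the follower genes Mfap4 and Eln, both of elastic fibres, fell with log2 fold changes of -3.41 and -3.30, while the other-cell marker sum fell from a control mean of 1560.4 to a re-added mean of 265 CPM. With that sum as a covariate Mfap4 and Eln gave -0.50 and -0.22 and did not pass, Xist passed with adjusted p = 0.0111, and 2796 genes passed in all. Re-added replicate 1 had a marker sum of 579 CPM but Xist at 0.0985 CPM, so the covariate need not remove Xist of other cells. Starved replicate 2, with a marker sum of 108 CPM, held Xist at 1.997 CPM. The Xist call therefore does not show a change in MIN6 cells. Leaving out re-added replicate 3 gave 5208 genes, and of the calls 50.2% were higher in the main test, 60.9% by limma on the TPM values, 42.2% with upper-quartile factors and 45.1% with RLE factors.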

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

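Leaving out the follower genes, matching libraries on the other-cell markers and taking the marker sum as a covariate were alternatives chosen after seeing the data. The other alternatives were fixed before the data were examined. Of 3794 values of named genes under all alternatives, 3696 kept their direction and their side of the threshold, 85 lost a call and 13 gained one. Of 2565 values of gene lists these counts were 2392, 97 and 76. No value that passed under both settings changed direction. The median of the β-cell secretory genes in starved against control went from -0.03 to 0.09 on the TPM + 0.1 values, where the list did not pass. The count of genes that differ among the 4 groups, 12103, ranged from 8793 to 12387. In the simulated starved against control data edgeR found 22.4% of genes changed by 0.5 on the log2 scale. Those data gave 128 calls, against 6559 in the real comparison. The adjusted threshold depends on how many genes change, so this share does not carry over to the real data. How many small changes were missed there was not tested.

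DESeq2 called 2287 genes in Rap against re-added, where edgeR called 1344, with 1330 shared. It gave 983 genes changed in the same direction as in starved against control and 1317 changed in the opposite direction to re-addition. In simulated Rap against re-added data 28.6% of the 168 calls of DESeq2 were false, against 3.64% of 110 by edgeR. These shares depend on how many genes change, and the simulated counts took their spread from the edgeR fit. They therefore do not carry over to the real data. Whether part of the further calls of DESeq2 is false was not tested. With only the libraries of the 2 groups compared, 4199 genes passed in starved against control and 3959 in Rap against re-added. Without the follower genes 2046 passed in Rap against re-added, and with the marker sum as a covariate 2796 passed in re-added against control. For these last 3 settings the cause was not tested. Matched libraries gave 3417, 3552 and 3709 genes in starved against control, re-added against starved and Rap against starved. The overlaps fell to 339 genes in the same direction, and to 1435 and 534 in opposite directions. The matched fits hold fewer libraries, but a smaller fit need not lower the number of calls. With only the libraries of the 2 groups that number fell in starved against control and rose in Rap against re-added. How far fewer libraries account for the lower counts was not tested. In the matched fits each comparison with starved cells holds 1 starved library, and this lone sample is assumed to vary like the other groups.

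The correlation between Rap against re-added and starved against control, 0.47, was 0.11 with no filter on low counts. It was 0.31 and 0.30 on the TPM + 1 and TPM + 0.1 values, and 0.27 on TPM + 1 with no minimum. It was 0.20 without the follower genes, 0.0822 in matched libraries and 0.14 with the covariate. For the filter and the TPM values the cause was not tested. Leaving out each library in turn gave 635 to 2058 genes in Rap against re-added, 4940 to 8290 in Rap against starved and 5208 to 8838 in re-added against control. The correlation then ranged from 0.12 to 0.55, the overlap in the same direction from 360 to 875, and the overlap of Rap with re-addition in opposite directions from 458 to 1230.

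The replicate number as a block, a paired fit, gave 6512, 5970 and 1067 genes in the 3 main comparisons, of which 6195, 5838 and 1053 were also called without it. In the secondary ones it gave 6928 and 8109. It ended the calls of 3 named gene values and 2 list values and started 1 and 2. The labels give no meaning to the numbers. Of 18 pairs of libraries with the same number in different groups, 2 had a correlation of deviations over 0.1, starved with re-added replicate 1 (0.81) and starved with re-added replicate 2 (0.67). The other pairs did not, so the numbers were not taken to pair the libraries. Of the 12 libraries 4 correlated best with one of their own number.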

Other observations

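The genes named from the lists in the first 2 paragraphs are members with small adjusted p, picked after their values were seen. The tests on other-cell markers and on the correlation of Rap with starvation were also chosen after the result was seen, and those on ribosomal protein genes and on other splits of the libraries before it, apart from the values of single libraries for ribosomal protein genes, added after it. In starved against control, genes that charge tRNAs and genes that make amino acids rose more often than they fell. Among aminoacyl-tRNA synthetases 12 of 20 rose and 2 fell (median log2 fold change 0.46, camera adjusted p = 2.3e-05, but adjusted p = 0.352 with an estimated correlation), with Aars at 0.97 and Nars at 0.86 on the log2 scale. In the serine, one-carbon and amino acid synthesis list 12 of 22 rose and 5 fell (median log2 fold change 0.46, camera adjusted p = 0.000507, but adjusted p = 0.352 with an estimated correlation), with Gpt2, an alanine aminotransferase gene, at 1.86 and Shmt2 at 1.14. Of the p53 target genes 8 of 18 rose and 1 fell (median log2 fold change 0.34, camera adjusted p = 0.00199, and adjusted p = 0.0421 with an estimated correlation). Sesn2, an inhibitor of mTORC1, was at 1.35, the cell cycle inhibitor gene Cdkn1a at 0.96 and Bbc3, a gene of apoptosis, at 1.24. Sesn2 is also in the ATF4 list. The median of the p53 target list was 0.20 with upper-quartile factors. Of the immediate early genes 15 of 28 rose and 3 fell (median log2 fold change 0.41, camera adjusted p = 6.1e-05, but adjusted p = 0.223 with an estimated correlation), with Jun at 0.92 and Nr4a1 at 0.97, and a median of 0.26 with upper-quartile factors. Fatty acid synthesis genes went the other way: 2 of 18 rose and 9 fell (median log2 fold change -0.37, camera adjusted p = 0.00111, but adjusted p = 0.352 with an estimated correlation), with the desaturase gene Scd2 at -2.04, and the TPM + 1 values gave a median of -0.20. Of the DNA replication and mitosis genes 6 of 47 rose and 20 fell (median log2 fold change -0.15, camera adjusted p = 0.00109, but adjusted p = 0.511 with an estimated correlation), Ccne1 at -0.89 and Cdk1 at -0.79, with medians between -0.28 and -0.02 under other scalings. The lists of β-cell transcription factors and of the mTORC1 pathway did not pass and held members that moved both ways. Of 22 β-cell transcription factor genes 9 rose, Neurod1 (1.07) and Nkx2-2 (0.58) among them, and 5 fell, as Pdx1 did (camera adjusted p = 0.313). Of 36 mTORC1 pathway genes 13 rose, Rragd (1.57) among them, and 10 fell (camera adjusted p = 0.313). On re-addition, chaperone genes of the unfolded protein response rose in 14 of 26 cases and fell in 3 (median log2 fold change 0.27, camera adjusted p = 2.4e-05, but adjusted p = 0.36 with an estimated correlation), Pdia4 by 1.32 and Hspa5, which encodes BiP, by 0.79 on the log2 scale.

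With Rap, several further lists were lower than in re-added cells. Heat shock protein genes fell in 10 of 17 cases and rose in 1 (median log2 fold change -0.42, camera adjusted p = 6.7e-11, and adjusted p = 0.0152 with an estimated correlation), Hspa8 at -0.69 and Hspd1 at -0.64 on the log2 scale. Of the glycolysis and HIF1 targets 2 of 26 rose and 10 fell (median log2 fold change -0.24, camera adjusted p = 6.0e-08, and adjusted p = 0.0378 with an estimated correlation). Translation factor genes fell in 11 of 32 cases and rose in 2 (median log2 fold change -0.24, camera adjusted p = 2.5e-05, but adjusted p = 0.351 with an estimated correlation), and genes of the pentose phosphate pathway and nucleotide synthesis fell in 6 of 23 and rose in none (median log2 fold change -0.21, camera adjusted p = 6.5e-06, but adjusted p = 0.279 with an estimated correlation), Cad and Impdh2 among them at -0.55 and -0.42. In fatty acid synthesis 1 of 18 rose and 7 fell (median log2 fold change -0.35, camera adjusted p = 2.7e-06, but adjusted p = 0.19 with an estimated correlation), Fasn at -0.87 and Lpin1 at 1.19. Members of some lists were called both here and in starved against control. In the FoxO and insulin signalling list 9 of 22 genes rose in both and 0 rose in starved cells but fell with Rap, and in the lysosome and autophagy list these counts were 9 and 0 of 41. In the cholesterol list 13 of 25 fell in both. In the ATF4 list none of 34 rose in both, while 13 rose in starved cells and fell with Rap. The same held for 11 of 20 aminoacyl-tRNA synthetase genes, with 1 that rose in both, and for 8 of 22 serine and amino acid synthesis genes. Shmt2, Mthfd2, Asns and other genes of the synthesis list are also in the ATF4 list, so the counts of these lists are not independent. Other lists were mixed. Of 42 ribosome biogenesis genes 11 rose in starved cells and fell with Rap, 5 fell in both, and 22 rose on re-addition and fell with Rap. Of 32 translation factor genes 1 rose in both, 2 fell in both, 3 rose in starved cells and fell with Rap and 1 did the opposite. No gene of the β-cell secretory list was called in both. The 2 comparisons of Rap and starvation share no library, and whether the lists differ from each other was not tested.

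The other-cell markers differed 12.7 times between the highest and the lowest starved library, against 1.2, 5.43 and 1.08 times within the control, re-added and Rap groups, which argues against a response of MIN6 cells to the treatment as the whole cause. RNA of lung cells in some libraries is a candidate explanation: the 16 genes of a lung list summed to 1872, 120.2 and 846 CPM in the starved libraries, 15.6 times more in the first than in the second, with a rank correlation of 0.85 with the other markers. The abundant lung and immune transcripts Scgb1a1, Lyz2 and Cd74 went from 352, 495 and 441 to 27.2, 15.8 and 14.8 CPM between those libraries, Alb of liver stayed between 0.985 and 1.69 CPM in all 12, and 12 of the 16 lung genes still exceeded 1 CPM in the Rap libraries. A single source for all libraries is argued against by the ratio of Xist to Y-linked reads, 37.9 in starved replicate 3 and 0.0154 in re-added replicate 1, a 2465-fold difference (95% counting interval 682 to 20351, from 2 Xist reads in the latter). How such RNA came into the libraries, and whether it came before or after library preparation, stays open.

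Ribosomal protein genes were lower in starved than in control cells, with a median log2 fold change of -0.50. RNA of other cells as the whole cause is argued against: the marker sums were 1372, 108 and 651 CPM in the 3 starved libraries, and the median against the control mean was -0.53, -0.55 and -0.38 in them, while the control libraries lay between -0.21 and 0.28. With the marker sum as a covariate it was -0.47 and without the follower genes -0.59. The test set for this, the libraries matched on other-cell markers, gave -0.54, but it holds 1 starved library, and that lone sample is assumed to vary like the other groups. These genes are short, and genes outside the list matched to them on length and CPM had a median of -0.17 (95% interval -0.34 to -0.11). An effect of gene length cannot be told apart from a response of the list, because that interval reaches past 0.5 of the list's change. The list was still low 3 h after amino acids were given back. Its median against the control mean was -0.38, -0.32 and -0.49 in the re-added libraries, and 3 of 79 genes rose and 1 fell against starved cells. A response to the missing amino acids is the biological explanation the design offers and stays open.

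Rap against re-added and starved against control correlated at 0.47 over all genes. Genes of other cells that follow the libraries are a candidate explanation for most of it, because the correlation was 0.20 without the follower genes, 0.0822 in matched libraries, with starved replicate 1 as the lone starved sample, assumed to vary like the other groups, and 0.12 without re-added replicate 1, whose marker sum was the highest of its group. What remains could reflect a shared response to Rap and to starvation. Of the 631 genes changed in the same direction in both comparisons, 566 are not follower genes. Beside them 171 genes other than followers changed in opposite directions, and independent lists would give 282 in the same direction. The count of 631 thus rests mostly on genes other than the followers. Whether it reflects a shared response stays open.

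Other splits of the same libraries were counted, the real one included. Each comparison of 3 libraries with 3 allows 10 splits, too few for a share under 0.05. The real split gave as many genes in 1 of 10 in each of the 5 comparisons, with 6559, 6275, 1344, 7424 and 8304 genes. By edgeR the highest other split gave 0 genes at an adjusted p under 0.05 in all but re-added against starved, where re-added replicate 1 with starved replicates 1 and 3 against the rest gave 1635 genes, a split that follows the other-cell markers. For the lists adjusted within 1 comparison, the real splits gave 23, 18 and 16 lists in the 3 main comparisons and the highest other splits 20, 19 and 19, with as many lists as in the real one in 1, 3 and 9 of 10. The camera calls at the preset correlation are therefore best read beside the counts of genes and the p with an estimated correlation. Over 100 splits of the 12 libraries into 4 groups of 3, chance can be excluded for the 12103 genes that differ among the groups (1 split as large, highest other 3023). For the 631 genes changed in the same direction by Rap and starvation, 2 splits were as large (highest other 1608). For the 3129 in opposite directions in starvation and re-addition it was 1 split (highest other 1741). Most other splits mix the groups and yield hardly any calls. These 2 counts therefore restate that the groups differ and do not test whether the overlaps exceed chance. Chance cannot be excluded for the correlation of 0.47 (15 splits, highest other 0.87). For the 840 genes in opposite directions with Rap and on re-addition, 5 splits were as large (highest other 1634). Splits with 1570, 1085 and 1099 such genes put all control or all starved libraries together in the place of the shared re-added group. Real differences between groups enter those counts, so this test neither excludes chance for the 840 genes nor shows it. The same split of the libraries was the highest other one in 4 of these 5 results. It put together control replicates 1 and 2 with re-added replicate 1, control replicate 3 with starved replicates 1 and 3, starved replicate 2 with re-added replicate 3 and Rap replicate 1, and re-added replicate 2 with Rap replicates 2 and 3. Of the variance of the log2 other-cell marker sum 93.6% lay between its groups, the highest share of the 100 splits, against 69.7% in the real one, so it follows these markers. These shares were computed after the split had been seen.

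Some single values stood apart from their groups. Gm42418 measured 6073 CPM in starved replicate 2, 1969 and 3759.7 CPM in Rap replicates 2 and 3, and between 408 and 954 CPM in the other 9 libraries. Rn7sk measured 34.8, 7.6 and 12.9 CPM in the same 3 libraries and at most 3.15 CPM in the others. Mitochondrially encoded mRNAs rose in 7 of 13 cases in starved against control (median log2 fold change 0.77, camera adjusted p = 0.008, but adjusted p = 0.511 with an estimated correlation), 7 of the 13 are follower genes, and without these the median was 0.26 and the list did not pass. Interferon response genes fell in 6 of 23 cases and rose in 2, 21 of them follower genes. Of the fibroblast, leukocyte and endothelial markers, 0 of 11, 1 of 12 and 0 of 9 passed in starved against control, with median log2 fold changes of -1.20, -1.17 and -1.20. The leukocyte list passed by camera (adjusted p = 0.0383, but adjusted p = 0.705 with an estimated correlation), and the fibroblast and endothelial lists did not (adjusted p = 0.0543 and adjusted p = 0.076).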
